A study of Mus musculus with 4 samples.

How the data were processed

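Single-cell 3-prime RNA sequencing was done on 4 libraries of mouse thymus cells from mice with a loxP-flanked Fezf2 gene. Per the labels, 1 library belongs to each of the groups FoxN1_wt and FoxN1_Cre (the FoxN1 line) and B5t_wt and B5t_iCre (the B5t line), and the genotype labels of both Cre-negative libraries are the same. Per the submitters' processing notes, the authors made the matrices with Cell Ranger 7.0.1 on mm10. The deposited values are raw UMI counts per gene and barcode in filtered matrices, and all were whole numbers. Gene positions were taken from GENCODE M21 on GRCm38, the same build under another name; the authors' annotation version is not stated, so genes were matched by identifier. No sequencing reads and no cell annotation were used here.

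Cells were kept with at least 1000 UMIs, at least 500 genes and at most 15% mitochondrial UMIs. Scrublet, in scanpy 1.11.5, was run on each library to remove doublets. Its automatic threshold called 2, 2, 3 and 1 cells in FoxN1_wt, FoxN1_Cre, B5t_wt and B5t_iCre, so that doublets were in effect not removed, and removal of the 5% of cells with the highest doublet score in each library was added as an alternative. Counts were not corrected for background RNA from other cells of the suspension. They were scaled to 10000 per cell and log-transformed. From 3000 variable genes, chosen with the library as batch, Fezf2, Psmb11, Foxn1, Xist and the Y-linked, mitochondrial and ribosomal protein genes were left out. Clusters came from 40 principal components, 15 nearest neighbours and Leiden resolution 1 (leidenalg 0.10.2, igraph 0.11.9), with no integration of the libraries. The 48 clusters were named by 21 marker lists, for thymic epithelial cells (TECs) of 14 kinds and for 7 other cell types, and 13 of them were TECs. Clustering the TECs alone gave 35 sub-clusters.

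Within a line each group has 1 library, so values are given with exact 95% intervals (Clopper-Pearson for shares, conditional Poisson and binomial for ratios) and no p-value. Intervals cover counting error only. The replicated comparison set the 2 Cre-positive against the 2 Cre-negative libraries, with 2 residual degrees of freedom. Its p-values measure only the spread between these libraries, and it averages over 2 Cre drivers. An exact permutation of these libraries cannot give a p below 0.333. Counts were summed per library and cell class and tested with edgeR 4.0.16 quasi-likelihood (TMM, filterByExpr, Benjamini-Hochberg, threshold 0.05) in classes with at least 30 cells in each library, and in all TECs summed. Errors of log2 fold changes are standard errors of this fit (n = 2 libraries against 2). Shares of classes were tested with edgeR quasi-likelihood on cell counts with the number of TECs as library size. Fold changes within a line were log2 ratios of CPM (counts scaled to the total of the library's class, times 1e6) with 5 CPM added. TMM moved the median of all genes by 0.11 and 0.18 (log2, FoxN1 and B5t line) in Aire-high cells, by 0.13 and 0.09 in keratinocyte-like cells, and by at most 0.06 elsewhere; edgeR changes are relative to the TMM scaling and changes within a line to total counts.

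A total of 20 gene lists and the 21 marker lists were tested with camera (limma 3.58.1), two-sided, with a preset inter-gene correlation of 0.01, and adjusted within a class over the lists of each kind with at least 3 measured members; estimated correlations were an alternative. The gene lists were Fezf2-associated antigens recalled from textbook accounts, classical Aire-dependent antigens, class II and class I antigen presentation, TNF-family receptors and NF-kB, thymic chemokines, partners of promiscuous expression, TEC identity factors, the tuft-cell pathway, keratinization, liver, pancreas, gut, mammary and salivary, nervous system and testis genes, interferon response, immediate-early stress genes, mitochondrial transcripts and sex-linked genes. Lists overlap (Krt10 is in the Fezf2-associated and the keratinization list). Within a line, a list's median was ranked among 10000 random lists matched on expression. Lists, tests, filters, the naming rule and the settings to be varied were fixed before the data were examined. The sub-clusters of TECs and the tests of their shares are an exception. They were added after the classes had been seen.

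Named genes were Fezf2, Psmb11, Foxn1 and Aire, and the 10 highest and 10 lowest fold changes in Aire-high cells (5 and 5 in other classes and in all TECs) past the threshold, with a mean of at least 20 CPM in the higher arm and 1 direction in both lines. Open places went to genes below the threshold with at least 20 counts, ranked by the smaller of the 2 lines' changes. Up to 4 members of each described list were taken by threshold and mean CPM.

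The settings varied were RLE normalization, no filter on low counts, the line as a block, leaving out each library, DESeq2 1.42.0, doublets kept, a mitochondrial limit of 5%, resolution 2, classes taken from the nearest Cre-negative cells, cells thinned to 2000 UMIs, other denominators of shares, a prior of 1 CPM, a minimum of 100 CPM and TMM-scaled CPM. Settings added after seeing the data were the doublet-score limit, male cells only, leaving out clusters of low UMI number or with genes of other cell types, and clustering without the genes that differed between the arms.

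The steps were tested on simulated data with 100 genes changed by log2 1 and 100 by log2 2 in each comparison. At log2 1, edgeR recovered 44 in Aire-high, 68 in Ccl21-high, 33 in cortical and 4 in keratinocyte-like cells and 17 in all TECs. At log2 2 it recovered between 79 and 99. Over both sizes, false calls numbered 24, 25, 20, 15 and 11 in the same order. In each comparison the false part of the calls was thus above the threshold of 0.05. For shares, 100 simulations with 1 class raised and 1 lowered 4-fold recovered them 93 and 94 times, with 26 false calls in 700 tests of unchanged classes. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, anndata 0.12.19, matplotlib 3.10.9 and R 4.3.3.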

Results

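Transcripts of single thymus cells were counted in 4 libraries from mice whose Fezf2 gene, which codes for a transcription factor of medullary thymic epithelial cells (mTECs), carries loxP sites. FoxN1_wt and FoxN1_Cre come from a line with a Cre driver named for Foxn1, a transcription factor needed for all thymic epithelium. B5t_wt and B5t_iCre come from a line with a driver named for the proteasome subunit B5t, coded by Psmb11, which is active in cortical TECs (cTECs) and in progenitors of mTECs. Each of the 4 groups has 1 library, so single values have no replicate error. FoxN1_wt held 8027 barcodes with 111945478 UMIs, FoxN1_Cre 9819 with 122783387, B5t_wt 8804 with 115478085 and B5t_iCre 8379 with 107929059. Of these, 5147, 6428, 6167 and 6193 cells were kept, at medians of 17084, 14974, 14773 and 13028 UMIs per cell. The kept cells held 1105 TECs in FoxN1_wt, 735 in FoxN1_Cre, 1549 in B5t_wt and 2327 in B5t_iCre, and the rest were mainly thymocytes, macrophages, dendritic cells, fibroblasts and endothelial cells. By their Y-linked and Xist UMIs, 36.6% of kept cells were male and 46.03% female in FoxN1_wt, 17.1% and 65.6% in FoxN1_Cre, and 38.2% and 42.6% in B5t_wt. In B5t_iCre 79.8% were male and 0.05% (3 cells) female, with the rest unclear, so that nearly all female cells of the B5t line are in its Cre-negative library.

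The first comparison asked what the labels predict for the floxed gene and the driver genes. Fezf2 (ENSMUSG00000021743, GRCm38 chromosome 14, 12342094 to 12348189) was higher, not lower, in the Aire-high mTECs of the library labelled with Cre in both lines. It stood at 341.0 CPM in FoxN1_wt and 866.2 CPM in FoxN1_Cre, a ratio of 2.54 (95% interval 2.42 to 2.67), and at 493.8 CPM in B5t_wt and 1089 CPM in B5t_iCre, a ratio of 2.21 (2.14 to 2.27). Across the lines edgeR gave a log2 fold change of 1.39 ± 0.23 with an adjusted p of 0.101, which did not pass. A Fezf2 UMI was found in 74.3% of Aire-high cells of FoxN1_wt, 83.9% of FoxN1_Cre, 75.8% of B5t_wt and 87.6% of B5t_iCre, at medians of 16355, 22635, 16767 and 22263 UMIs per cell. The background, the share in cTECs, was 2.26%, 4.85%, 9.20% and 7.82% at medians of 30074.5, 26725.5, 18141 and 11348 UMIs. The labels do not say which exons are floxed, and tags at the 3-prime end may lie outside the deleted part, so these counts do not check the deletion.

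Psmb11 (ENSMUSG00000072423, chromosome 14, 54621433 to 54629556) was lower in the cTECs of B5t_iCre, at 430.6 CPM against 1112 CPM in B5t_wt, a ratio of 0.387 (0.375 to 0.40); in the FoxN1 line the ratio was 0.853 (0.832 to 0.873). Foxn1 (ENSMUSG00000002057, chromosome 11, 78357577 to 78386558) was higher in the cTECs of FoxN1_Cre, at 370.8 CPM against 193.3 CPM in FoxN1_wt, a ratio of 1.92 (1.82 to 2.02); in the B5t line the ratio was 0.929 (0.873 to 0.989). Aire (ENSMUSG00000000731, chromosome 10, 78030022 to 78043610), the other known regulator of self-antigen expression in mTECs, had ratios of 0.880 (0.838 to 0.924) in the FoxN1 line and 0.815 (0.787 to 0.845) in the B5t line in Aire-high cells. None of the 3 passed edgeR across the lines: log2 -0.68 and adjusted p 1.0 for Psmb11, 0.49 and 1.0 for Foxn1, and -0.08 and 0.837 for Aire. Without FoxN1_Cre the Foxn1 value was -0.22; the Aire value was 0.02 without FoxN1_wt and 0.05 without B5t_iCre.

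**Figure D1:**
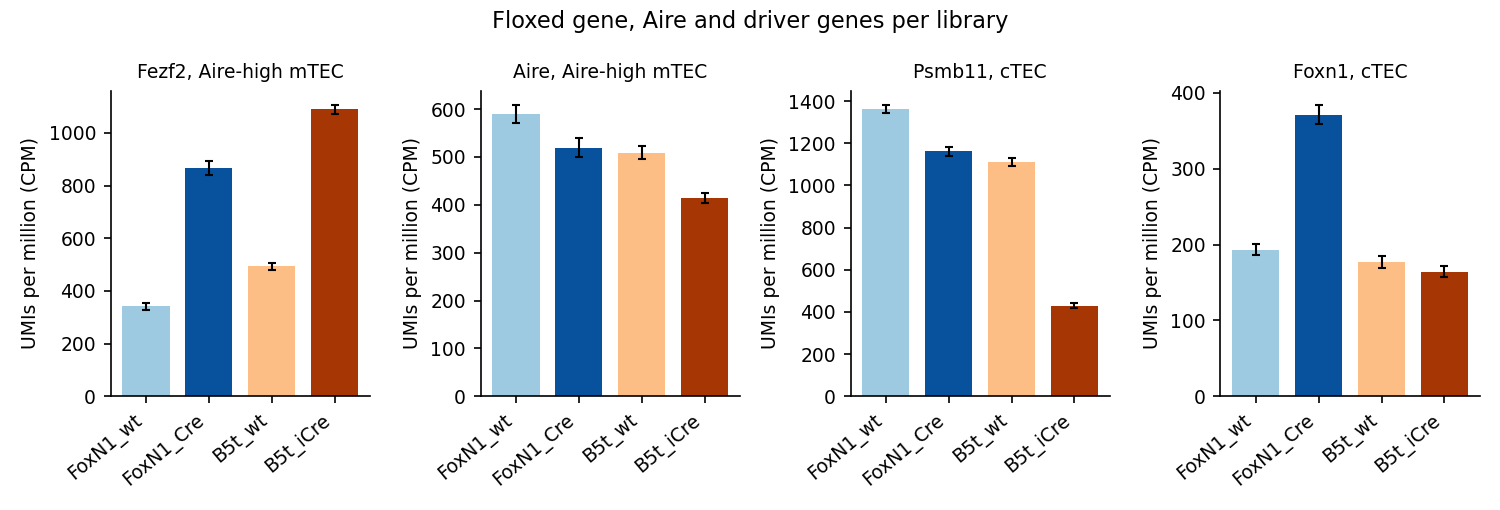
CPM of Fezf2 and Aire in Aire-high mTECs and of Psmb11 and Foxn1 in cTECs, 1 bar per library with its exact 95% counting interval. Fezf2 stood at 866.2 and 1089 CPM in the libraries labelled with Cre and at 341.0 and 493.8 CPM in their Cre-negative libraries.

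The comparison of cell classes asked how the make-up of the thymic epithelium differed with Cre. Tuft-like mTECs, which resemble the chemosensory cells of gut and airways, made up 2.99% of TECs in FoxN1_wt (33 cells; 95% interval 2.06 to 4.17) and 0.408% in FoxN1_Cre (3 cells; 0.084 to 1.19), and 2.07% in B5t_wt (32 cells; 1.42 to 2.90) and 0.301% in B5t_iCre (7 cells; 0.121 to 0.619). Their share fell by 2.87 on the log2 scale (edgeR, adjusted p = 0.0262), with ratios of 0.137 (0.027 to 0.436) in the FoxN1 line and 0.146 (0.054 to 0.336) in the B5t line. Keratinocyte-like mTECs, which follow the Aire-expressing stage, rose from 3.71% (2.68 to 5.0) to 9.66% (7.62 to 12.03) in the FoxN1 line and from 4.52% (3.54 to 5.68) to 17.4% (15.8 to 18.96) in the B5t line, a log2 change of 1.72 (adjusted p = 0.0473). An unnamed TEC cluster (cluster 31) fell by 1.23 on the log2 scale (adjusted p = 0.0473), from 43 to 14 cells and from 67 to 38 cells. The tuft-like call was lost without FoxN1_wt (-2.57, adjusted p = 0.142) and without B5t_wt (-3.09, 0.0853), the keratinocyte-like call without FoxN1_wt (1.58, 0.441) and without B5t_wt (1.87, 0.309), and the call of cluster 31 without FoxN1_wt (-1.29, 0.441), B5t_wt (-1.14, 0.569) or B5t_iCre (-1.11, 0.0528). With the 5% of cells of highest doublet score removed none of the 3 passed (adjusted p = 0.0642, 0.0893 and 0.117).

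Sub-clusters were formed and counted over all TECs, a step added after the classes had been seen. Among those whose most frequent class was keratinocyte-like, one with secretory genes passed the test. This sub-cluster, led by Bpifa1 and Ltf, which code for secreted antimicrobial proteins of airways and glands, with Gsto1 and Krt6a, held 12 cells in FoxN1_wt, 52 in FoxN1_Cre, 21 in B5t_wt and 308 in B5t_iCre, a log2 change in share of 3.05 (adjusted p = 0.0196). The sub-cluster with Krt10, Lor and Krtdap, genes of the cornifying epidermis, held 28, 16, 41 and 72 cells, a log2 value of 0.04 that did not pass (adjusted p = 0.970). Another with secretory genes, among them Agr2 and Muc5b, held 4, 4, 6 and 17 cells and did not pass either (log2 0.79, adjusted p = 0.456). Clustered again without the genes that differed between the arms, the class kept 506 of its 586 cells, and its share missed the threshold (log2 1.61, adjusted p = 0.0669), with ratios of 2.55 and 3.403 in the FoxN1 and B5t lines.

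Aire-high mTECs were 35.6% of TECs in FoxN1_wt, 32.1% in FoxN1_Cre, 41.9% in B5t_wt and 28.4% in B5t_iCre (log2 -0.36, adjusted p = 0.343). Ccl21-high mTECs, which secrete the chemokine that draws thymocytes into the medulla, were 15.1%, 17.6%, 16.9% and 26.6% (log2 0.47, 0.343), cTECs were 36.02%, 36.5%, 28.1% and 20.3% (log2 -0.18, 0.684), and microfold-like mTECs were 1.99%, 1.63%, 1.55% and 1.46% (log2 -0.20, 0.659). These classes did not pass. Thymocyte genes led some TEC sub-clusters whose most frequent class was cTEC. A sub-cluster led by Trbc1, Cd8a and Cd3d held 80, 49, 67 and 50 cells in FoxN1_wt, FoxN1_Cre, B5t_wt and B5t_iCre, at a median of 71099 UMIs. Another, led by Themis and Rag1, held 77, 53, 52 and 55 cells, at a median of 50312 UMIs. Their cTECs were not left out of the shares, CPM or gene tests of cTECs. The whole class had medians of 30074.5, 26725.5, 18141 and 11348 UMIs in the same order of libraries. A typical cell of these sub-clusters thus weighs more in the summed counts of cTECs. Whether doublets with thymocytes are among them was not tested. Without FoxN1_Cre the remaining libraries gave calls for Aire-high cells (-0.45, adjusted p = 0.0448), Ccl21-high cells (0.73, 0.00598) and cTECs (-0.65, 0.0106), and without FoxN1_wt or B5t_iCre the cTEC value was 0.01 or 0.19.

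**Figure D2:**
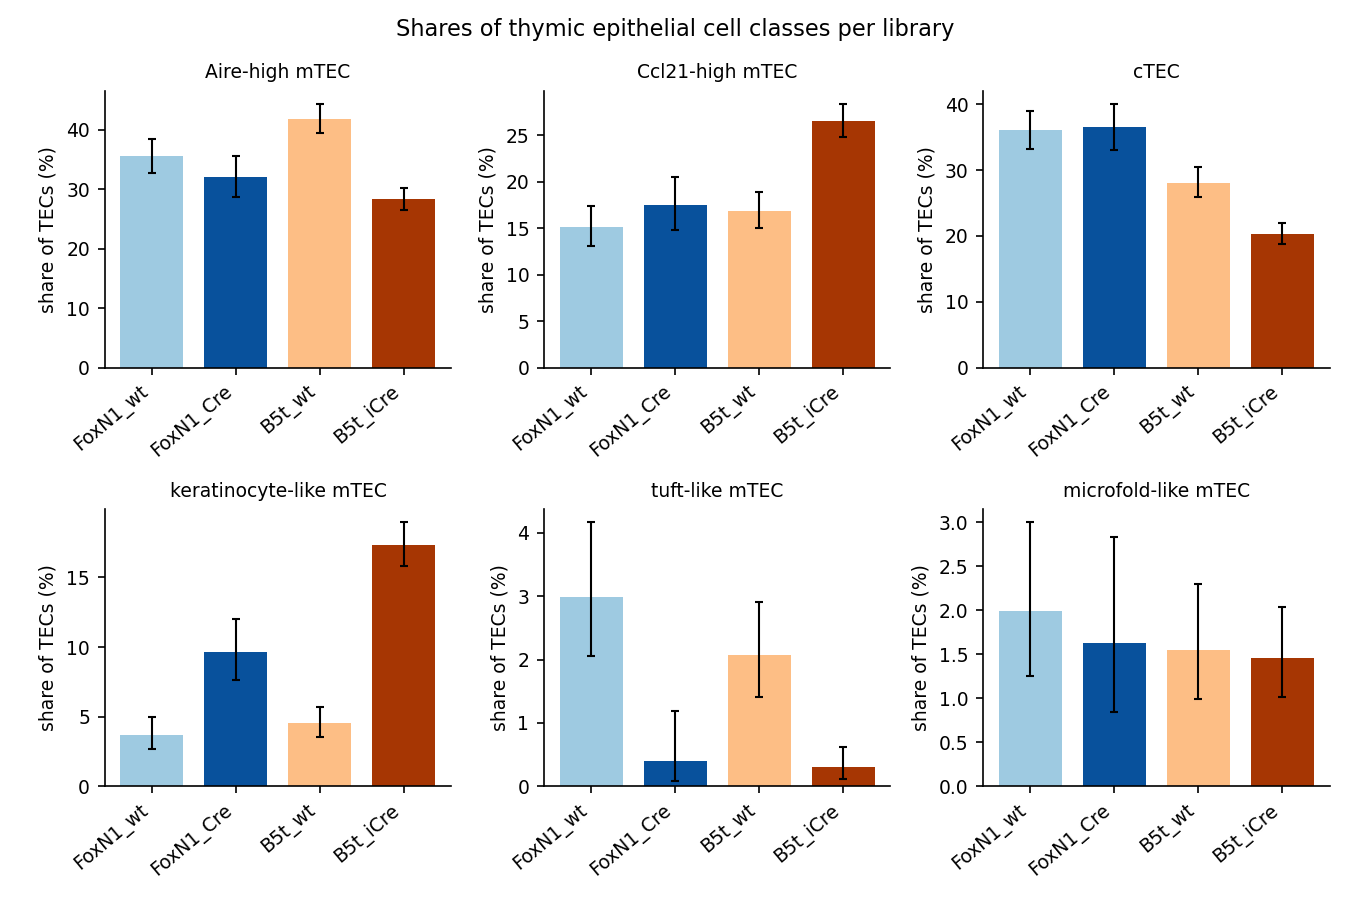
Percent of TECs in the Aire-high, Ccl21-high, cortical, keratinocyte-like, tuft-like and microfold-like classes, 1 bar per library with its exact 95% interval. Tuft-like cells stood at 2.99% and 2.07% in the Cre-negative libraries and at 0.408% and 0.301% with Cre, and keratinocyte-like cells at 3.71% and 4.52% against 9.66% and 17.4%.

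Within Aire-high mTECs, the class that expresses most tissue-specific self-antigens, the question was which genes differ with Cre. A total of 12 of 18852 genes passed edgeR, 8 higher and 4 lower, each in the same direction in both lines and with an adjusted p of 0.0489. The genes that rose included Lamp1, a lysosomal membrane protein (1.955 ± 0.09 on the log2 scale), Hspe1 (1.83 ± 0.12) and Hspd1 (1.38 ± 0.09), the mitochondrial chaperonins, and Bcl2a1d, of an anti-apoptotic gene family with near-identical copies (1.70 ± 0.10). Hspd1, Hspe1 and Mob4 (1.48 ± 0.10) lie side by side on chromosome 1 (55077835 to 55154899). The others that rose were Dkkl1, a gene of sperm (2.70 ± 0.18), the axon guidance ligand Slit1 (1.75 ± 0.11) and the unnamed gene Gm49542 (1.74 ± 0.10). The genes that fell were Hpse2, a heparanase-like protein (-1.996 ± 0.11), the proteoglycan Spock3 (-1.93 ± 0.11), the carbonyl reductase Cbr2 (-1.71 ± 0.10) and the gut hormone gene Pyy (-1.55 ± 0.10). The values were close in both lines: Lamp1 stood at 253.0 and 266.9 CPM without Cre and at 902.9 and 901.8 CPM with Cre, and Spock3 at 436.9 and 451.7 CPM against 112.1 and 96.6 CPM. The test favours genes whose libraries of an arm lie close, so this closeness is no separate evidence. Sub-clusters of TECs whose most frequent class was Aire-high differed in share with Cre as well. Of the TEC sub-clusters, chosen here after their values were seen, one led by Resp18, Smtnl1, Spock3, Fabp9 and Ptgs2 held 87 cells in FoxN1_wt, 2 in FoxN1_Cre, 145 in B5t_wt and 15 in B5t_iCre (log2 -4.07 in share of TECs, adjusted p = 0.0155). Another, whose leading genes include Ccr7 and Gm49542, held 2, 49, 11 and 175 cells (3.91, 0.0186). The sub-clusters were formed on expression that includes these genes, and a change in make-up was not separated from a change within cells. The class held 6885273 UMIs in FoxN1_wt, 5227475 in FoxN1_Cre, 12044532 in B5t_wt and 15211387 in B5t_iCre.

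Larger changes with more spread did not pass. They include Wfdc12 (log2 3.48, adjusted p = 0.0898) and the protease inhibitor gene Stfa2 (4.88, 0.123) among higher values. Among lower values were Smtnl1 (-3.07, 0.0666), the prostaglandin synthase gene Ptgs2 (-2.54, 0.0664), Resp18 (-2.22, 0.0666), Sgcz (-2.53, 0.0644), Fabp9 (-2.74, 0.161) and 1810006J02Rik (-2.67, 0.0666). The 12 calls lie close to the threshold. With the line as a block the count was 0, as it was without any 1 of the 4 libraries; the 12 genes had adjusted p up to 0.0662 with the block and up to 0.387 without FoxN1_wt, 0.0924 without FoxN1_Cre, 0.302 without B5t_wt and 0.110 without B5t_iCre. All 12 kept their direction and an unadjusted p under 0.05 in these fits; DESeq2 passed 823 genes, these 12 among them, and edgeR had 3370 genes at an unadjusted p under 0.05.

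**Figure D3:**
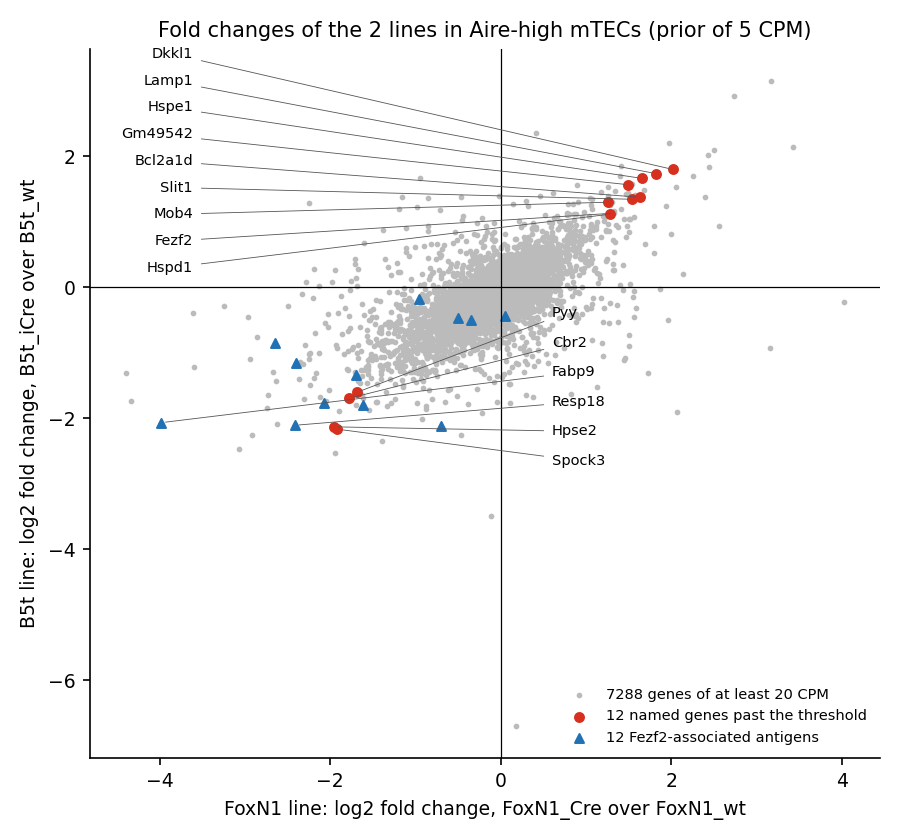
Log2 fold change of Cre against Cre-negative in Aire-high mTECs, FoxN1 line on the x axis and B5t line on the y axis, 1 point per gene with a mean of at least 20 CPM, with the genes past the threshold named. The values had a Pearson r of 0.625 across 7288 genes.

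Genes that textbook accounts link to Fezf2 were lower in Aire-high cells. The list's 12 members had a median log2 fold change of -1.95 (camera, adjusted p = 8.44e-05), but the adjusted p was 0.825 with an estimated correlation. None passed over all genes, and 7 were lower when adjusted over the list alone, among them Fabp9, of sperm (-2.74), Resp18, of neuroendocrine cells (-2.22), the apolipoprotein gene Apoc3 (-1.62) and Nol4 (-1.95). The list's medians were -1.66 in the FoxN1 line and -1.26 in the B5t line, below all of the 10000 random lists. Classical Aire-dependent antigens did not move together: the median of 10 members was -0.02 (adjusted p = 0.754), with 0 calls adjusted over the list alone, and members were Csn2 at 0.07, S100a8 at 0.23, Tff3 at 0.32 and Pcp4 at -0.12. Their medians were -0.08 in the FoxN1 line (percentile 29.7 of random lists) and -0.48 in the B5t line (percentile 0.12).

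Class II antigen presentation genes were higher in Aire-high cells, with a median of 0.25 over 17 members (adjusted p = 0.00675; adjusted p = 0.825 with an estimated correlation). Adjusted over the list alone, 8 were higher, such as H2-Aa (0.71), H2-Eb1 (0.59), Cd74 (0.55) and H2-Ab1 (0.49), and Ciita, which codes for their transactivator, was lower (-0.52); none passed over all genes. Immediate-early stress genes were also higher, with a median of 0.61 over 15 members (adjusted p = 0.00232; adjusted p = 0.970 with an estimated correlation). No member passed over all genes and 5 were higher adjusted over the list alone, while the members of highest expression were Jund at 0.31, Junb at 0.15, Hspa1a at 0.03 and Hspa1b at 0.06. Their medians were 0.25 and 0.54 in the FoxN1 and B5t lines, and the list was also higher with Cre in all 6 classes of cells that are not TECs, in both lines, with medians from 0.17 to 0.98; in the B5t line 9 of its 15 members were above 0 in dendritic cells and 8 in B cells.

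The other 16 gene lists in Aire-high cells did not pass camera, with adjusted p between 0.539 and 0.970, and no member of any passed over all genes. Adjusted over the list alone, 5 pancreas genes passed, 4 each of the class I list and of the TEC identity factors, 3 chemokines, 3 keratinization genes, 2 each of the nervous system and interferon lists, and 1 each of the TNF-family, partner and gut lists; the tuft-cell, liver, mammary, testis, mitochondrial and sex-linked lists had 0. The medians of the tuft-cell and liver lists were -0.45 and -0.51. For TEC identity factors the median was -0.06 where mean and test pointed up, and for the testis and sex-linked lists the medians were 0.03 and 0.38 where the test pointed down. Among markers, those of enterohepatic-like mTECs were lower (camera, median -0.82, adjusted p = 0.0116) and those of erythroid cells higher (1.72, 0.00942). Both had an adjusted p of 0.678 with an estimated correlation, and the other 19 marker lists did not pass. Erythroid cells numbered 18, 26, 2 and 15 in FoxN1_wt, FoxN1_Cre, B5t_wt and B5t_iCre. Their background RNA was not separated from expression in Aire-high cells.

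**Figure D4:**
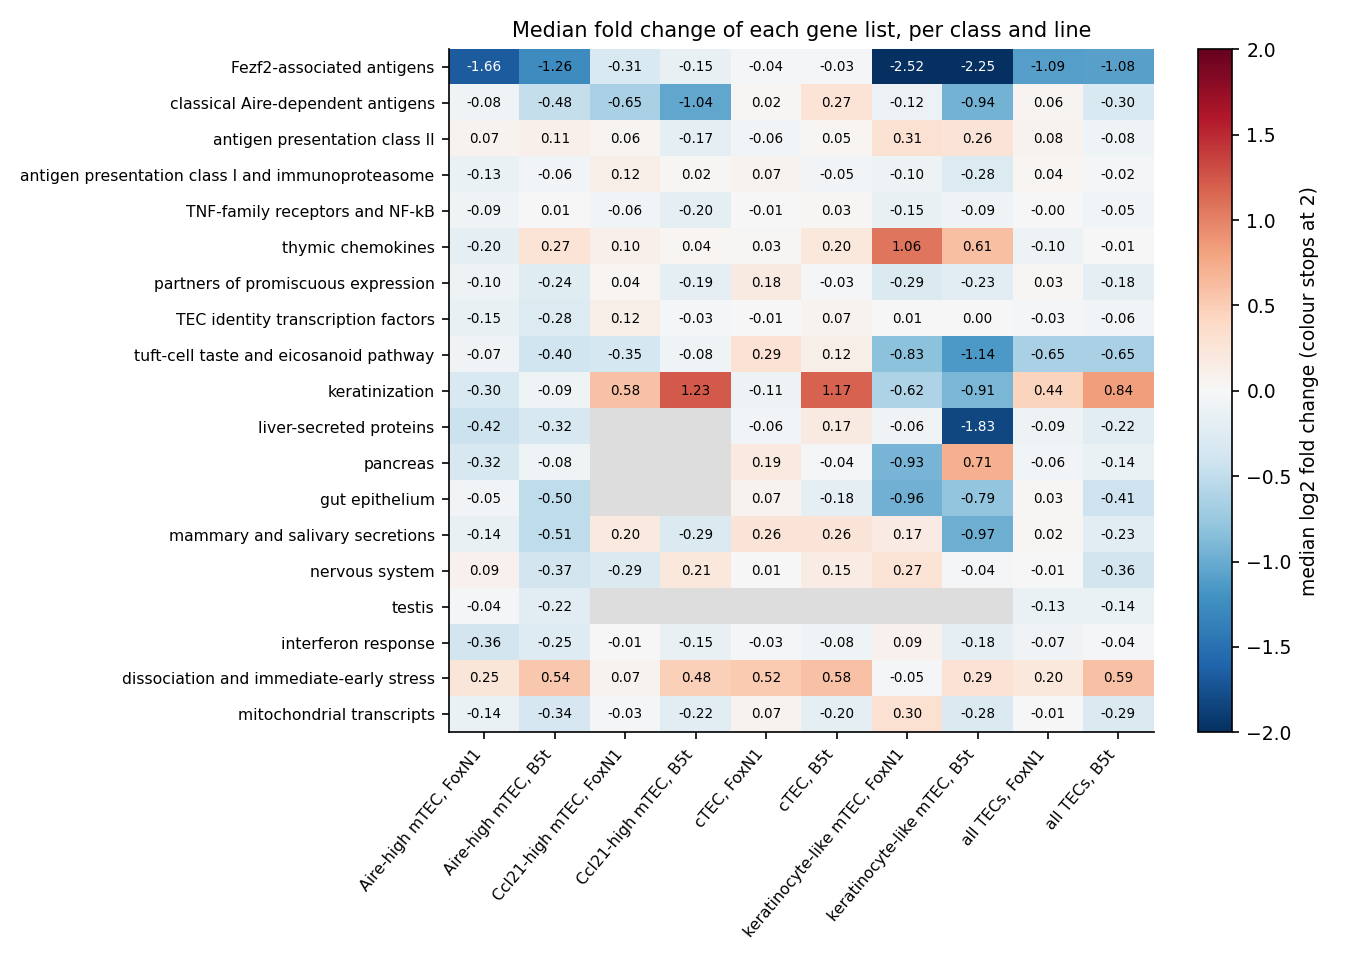
Median log2 fold change of each fixed gene list within each line, Cre against Cre-negative with 5 CPM added, 1 row per list and 1 column per cell class and line. The sex-linked list is left out. The edgeR medians of the Fezf2-associated list across the lines, which are not drawn, were -1.95 in Aire-high cells, -4.18 in keratinocyte-like cells and -1.71 in all TECs.

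In keratinocyte-like mTECs 44 of 11557 genes passed edgeR, 17 higher and 27 lower. The genes named here were chosen to have 1 direction in both lines. Among the named genes, those that rose were Lifr, the receptor of leukaemia inhibitory factor (log2 3.92 ± 0.42, adjusted p = 0.0467), Gm15943 (3.20 ± 0.35, 0.0484), the interferon-family gene Ifit1bl1 (3.19 ± 0.24, 0.0410), the sialyltransferase gene St6galnac1 (2.95 ± 0.31, 0.0467) and F3, which codes for tissue factor (2.70 ± 0.26, 0.0410). Lower were Lgals7, a galectin of stratified epithelium (-5.03 ± 0.50, 0.0411), the suprabasal keratin Krt10 (-4.64 ± 0.31, 0.0410) and Oas1f (-4.24 ± 0.25, 0.0409). Krt10 stood at 1520.0 CPM in FoxN1_wt, 52.5 CPM in FoxN1_Cre, 2066 CPM in B5t_wt and 78.9 CPM in B5t_iCre. The named genes also include Gsdmc, of the pore-forming gasdermins (22, 0, 51 and 4 UMIs in the 4 libraries), and Stfa1 (54, 0, 88 and 10 UMIs), at which fitted folds are no bounds. The class held 41, 71, 70 and 404 cells. Counted over all TECs, the sub-cluster with Krt10 and Lor held 28, 16, 41 and 72 cells, and that with Bpifa1 and Ltf 12, 52, 21 and 308. Not all of these cells need be in the class. A change in the make-up of the class was not separated from a change within cells. Without B5t_wt the count was 0, without FoxN1_wt 1, without FoxN1_Cre 110 and without B5t_iCre 152; it was 4 in male cells alone, 130 with the line as a block, 115 when clustered without the differing genes (41 of the 44 among them) and 509 by DESeq2.

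Among the fixed lists, Fezf2-associated antigens were lower in this class: 7 members had a median of -4.18 (adjusted p = 2.95e-05; adjusted p = 0.480 with an estimated correlation), of which Krt10 passed over all genes and all 7 when adjusted over the list alone, with Apoc3 at -4.57, Fabp9 at -4.18 and Resp18 at -2.22. Keratinization genes were lower, with a median of -0.84 over 21 members (0.00740; adjusted p = 0.480 with an estimated correlation); Krt10 and Krt77 (-2.09) passed over all genes, 7 were lower and 2 higher adjusted over the list alone, and Krtdap stood at -1.14 and Spink5 at 0.01. Tuft-cell genes were lower, with a median of -1.56 over 10 members (0.00302; adjusted p = 0.853 with an estimated correlation) and 4 members lower adjusted over the list alone, and the examples were Pou2f3 at -2.11, Ltc4s at -1.57, Gng13 at -1.18 and Itpr3 at -0.81. Thymic chemokines were higher, with a median of 0.95 over 15 members (0.00145; adjusted p = 0.480 with an estimated correlation) and 5 calls adjusted over the list alone, and the examples were Ccl25 at 2.80, Ccl6 at 2.28, Ccl5 at 1.90 and Ccl21a at 1.302. The other 15 lists tested did not pass, with adjusted p between 0.0645 and 0.832. The share of tuft-like cells was also lower with Cre (log2 -2.87). Their background RNA was not separated from the change of the tuft-cell list in this class. Markers of secretory mTECs were higher in the class (median 1.31, adjusted p = 0.0295), and those of keratinocyte-like (-0.61, 0.0251), tuft-like (-1.55, 0.0251), neuroendocrine-like (-2.79, 0.0251) and enterohepatic-like (-2.17, 0.0295) mTECs lower; all had an adjusted p of 0.618 with an estimated correlation.

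In Ccl21-high mTECs edgeR passed 0 of 12761 genes, with 561 at an unadjusted p under 0.05, 14 by DESeq2, 2 without FoxN1_Cre and 4 without B5t_wt. None of the named genes, ranked by the smaller of the lines' changes, passed. Those with higher values were the cornified envelope gene Sprr1a (log2 1.81, adjusted p = 0.776), the protease inhibitor gene Cst6 (1.66, 1.0), Fyb2 (1.64, 0.575), the phospholipase gene Pla2g7 (1.64, 1.0) and the immediate-early gene Fosb (1.41, 0.726). Those with lower values were Sox11, a developmental transcription factor (-2.75, 0.726), Il23r, a cytokine receptor (-2.16, 0.303), Entpd3 (-2.08, 0.826), the cartilage protein gene Matn1 (-2.03, 1.0) and Cpxm1 (-1.53, 0.812). Keratinization genes were higher as a list, with a median of 1.01 over 5 members (adjusted p = 0.00119; adjusted p = 0.856 with an estimated correlation). Sprr1a, Dmkn (1.79) and Sbsn (1.01) passed adjusted over the list alone, and Krtdap (0.67) and Krt10 (0.06) did not. The share of keratinocyte-like cells was also higher with Cre (log2 1.72). Background RNA of such cells, or such cells placed in this class, were not separated from a change within Ccl21-high cells. Immediate-early genes had a median of 0.37 (0.000256; adjusted p = 0.856 with an estimated correlation), and Fosb passed adjusted over the list alone; the list's medians were 0.07 in the FoxN1 line and 0.48 in the B5t line. The other 14 lists tested had adjusted p between 0.196 and 0.951. Markers of keratinocyte-like mTECs (0.67, 0.00727), B cells (0.64, 0.0226) and cTECs (0.29, 0.0269) were higher and enterohepatic markers lower (-0.60, 0.0425), all with adjusted p of 0.688 or more with an estimated correlation.

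In cTECs edgeR passed 0 of 15053 genes, with 357 at an unadjusted p under 0.05, 16 by DESeq2, 3 without FoxN1_wt and 1 without B5t_iCre. All genes named by the same ranking had an adjusted p of 1.0. Those with higher values were S100a4 (log2 2.24), the chemokine gene Ccl21a, which has near-identical copies (2.01), the growth factor gene Igf1 (1.59), Fosb (1.47) and Fos (1.42), and those with lower values Inmt (-0.99), Aox2 (-0.86), Olfr920 (-0.78), Amn (-0.76) and Ctnna3 (-0.60). Immediate-early genes were higher as a list, with a median of 0.49 (adjusted p = 2.73e-09; adjusted p = 0.894 with an estimated correlation). Of them, 3 passed adjusted over the list alone, and the members of highest expression were Jun (0.53), Junb (0.49), Btg2 (0.27) and Jund (0.20). The tuft-cell list had a median of 0.31 over 11 members (0.0129; adjusted p = 0.894 with an estimated correlation) with no member past the threshold on either scale: Alox5ap stood at 0.92, Hpgds at 0.80, Itpr3 at 0.01 and Pou2f3 at -0.53. Markers of macrophages and dendritic cells moved with Cre in this class (median 1.91, adjusted p = 2.25e-09; adjusted p = 0.528 with an estimated correlation), and Alox5ap and Hpgds are also expressed in such cells. Fibroblast markers were higher too (0.69, 0.0236), and those of cTECs (-0.19, 0.0375), transit-amplifying TECs (-0.11, 0.0449) and enterohepatic-like mTECs (-0.86, 0.0224) lower, with adjusted p of 0.528 or more with an estimated correlation. The other 17 lists tested had adjusted p between 0.0845 and 0.921.

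Summed over all TECs, which includes the change in their make-up, edgeR passed 0 of 20909 genes, with 1635 at an unadjusted p under 0.05 and 414 by DESeq2; the count was 54 with the line as a block and 32 without FoxN1_Cre. By the same ranking, the genes named with higher values were Wfdc12 (log2 4.56, adjusted p = 0.370), Bpifa1 (3.25, 0.358), Ltf (3.02, 0.409), the cornified envelope gene Sprr2a3 (2.96, 0.536) and Gsto1 (2.85, 0.404). Those with lower values were the tuft-cell gene Rgs13 (-4.13, 0.358), Smtnl1 (-2.84, 0.358), Fabp9 (-2.65, 0.544), Ptgs2 (-2.38, 0.388) and Resp18 (-2.15, 0.479). Tuft-cell pathway genes were lower as a list, with a median of -0.93 over 18 members (1.76e-11) and 13 lower adjusted over the list alone, and examples were Gnat3 at -1.67, Pou2f3 at -0.93, Gng13 at -0.57 and Itpr3 at -0.18. Fezf2-associated antigens were lower too, with a median of -1.71 over 12 members (4.29e-08) and 7 lower adjusted over the list alone; both lists had an adjusted p of 0.251 with an estimated correlation. Keratinization genes (median 0.88 over 22 members, 4.12e-05) and immediate-early genes (0.54, 3.36e-06) were higher, with 6 higher and 2 lower, and 0, adjusted over the list alone, and an adjusted p of 0.775 for both with an estimated correlation; Sprr1a stood at 2.43, Sbsn at 2.31, Spink5 at 1.73 and Krtdap at 0.91. The other 16 lists had adjusted p between 0.324 and 0.930. Of the marker lists, tuft-like (-0.96, 5.06e-14), enterohepatic-like (-0.76, 0.000658) and transit-amplifying (-0.47, 0.0297) markers were lower by camera. Secretory (1.08, 0.000128), keratinocyte-like (1.06, 0.0186) and erythroid (2.36, 0.0307) markers were higher. With an estimated correlation their adjusted p was from 0.292 to 0.814. The erythroid value was not separated from background RNA here either.

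The last comparison asked whether both Cre drivers moved the same genes. Across genes, which are not independent replicates, the fold changes of the lines had a Pearson r of 0.625 and a Spearman rho of 0.639 in Aire-high cells, where the crossed differences (FoxN1_Cre against B5t_iCre, and FoxN1_wt against B5t_wt) gave r = 0.261. In keratinocyte-like cells r was 0.549 and rho 0.556 over 7422 genes, against a crossed 0.088. It was 0.118 (rho 0.130) in Ccl21-high cells and -0.008 (rho 0.161) in cTECs, below the crossed 0.328 and 0.563, and in all TECs it was 0.576 (rho 0.444) against 0.607. In Aire-high cells 53 genes were at least 2-fold higher in both lines and 129 at least 2-fold lower, 9 differed in opposite directions, and the crossed differences shared 34. With TMM-scaled CPM the counts were 76 higher and 84 lower, so the excess of lower genes depends on the scaling. In keratinocyte-like cells the counts were 119, 248, 30 and 68, and in cTECs 6, 0, 6 and 82.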

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

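For the values in this part the intervals of the lines lie on opposite sides of 1; with 1 library per group the difference between the lines was not tested, and no explanation of these values was weighed. Foxn1 in cTECs had a ratio of Cre to Cre-negative of 1.92 (95% interval 1.82 to 2.02) in the FoxN1 line and 0.929 (0.873 to 0.989) in the B5t line. TECs among all kept cells had ratios of 0.533 (0.485 to 0.585) and 1.496 (1.40 to 1.60) in the FoxN1 and B5t lines. Among cells that are not TECs, B cells had ratios of 2.68 (2.20 to 3.29) and 0.320 (0.248 to 0.411). Endothelial cells had ratios of 0.449 (0.381 to 0.528) and 3.29 (2.84 to 3.82), and fibroblasts or mesothelial cells 0.414 (0.361 to 0.475) and 1.36 (1.26 to 1.47). How cells were enriched before loading is not stated in the labels.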

How the results depend on the processing

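Alternatives chosen after the data were seen were the removal of the highest 5% of doublet scores, male cells only, leaving out low-UMI and mixed clusters, and clustering without the differing genes. Of the values of the comparisons under all alternatives, 319 were the same, 65 moved, 5 reversed, 5 became stronger and 32 weaker; for named genes 731 were the same, 56 stronger, 181 weaker and 3 reversed. The same, for a value with a test, means its direction and side of the threshold, and for a value without one, a place within the 95% interval of the main value; counts of genes are the same within 1.5 times the main count. Within-line ratios of the keratinocyte-like share stayed in these intervals under each alternative, but that of the FoxN1 line came down from 2.603 to 1.81 at the mitochondrial limit of 5%. In cells thinned to 2000 UMIs the within-line ratios were 2.77 for Fezf2 in the FoxN1 line, 0.718 for Aire in the B5t line, 0.806 and 0.359 for Psmb11 in the FoxN1 and B5t lines, and 2.16 and 0.805 for Foxn1, the last with an interval (0.625 to 1.04) that spans 1. Where a value changed the cause was not tested, except that leaving out a library leaves 1 residual degree of freedom and 1 arm with a lone library, assumed to vary like the others. Few cells limit tuft-like, microfold-like and cluster 31 counts. At a mitochondrial limit of 5% no tuft-like cluster was found. The tuft-like cluster had a median of 7.09% mitochondrial UMIs, so that this limit leaves out most of its cells. In cells thinned to 2000 UMIs no microfold-like cluster and no cluster 31 were found, and in clustering without the differing genes no microfold-like cluster. These settings give no value for those classes.

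Genes past the threshold, 12 in Aire-high cells, were 561 with no filter on low counts, 823 by DESeq2, and 0 with the block by line, doublets kept, the mitochondrial limit of 5%, classes from the nearest Cre-negative cells, the highest 5% of doublet scores removed, male cells only, without low-UMI clusters and when clustered without the differing genes. In keratinocyte-like cells (44) they were 1758 with no filter, 130 with the block by line, 509 by DESeq2, 28 at the mitochondrial limit, 148 at resolution 2, 93 from nearest cells, 4 in male cells and 115 when clustered without the differing genes. In Ccl21-high cells (0) they were 259 with no filter, 14 by DESeq2 and 1 in male cells; in cTECs (0) 16 by DESeq2; in all TECs (0) 54 with the block by line and 414 by DESeq2. Leaving out each library gave 0 to 0 in Aire-high, 0 to 152 in keratinocyte-like, 0 to 4 in Ccl21-high and 0 to 3 in cortical cells and 0 to 32 in all TECs.

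Log2 changes of shares that lost their call were, for cluster 31, -1.09 with TMM over the classes, -1.34 without cTECs in the denominator, -1.22 with doublets kept, -1.62 with the highest 5% of scores removed, -1.12 in male cells and -1.43 when clustered without the differing genes; for keratinocyte-like cells 1.73 with doublets kept, 1.78 with the 5% removed and 1.61 when clustered without the differing genes; and for tuft-like cells -2.79 with the 5% removed. Microfold-like cells reversed to 0.12 at the mitochondrial limit of 5% and 0.31 in male cells. Without each library in turn the ranges were -3.09 to -2.57 for tuft-like cells, 1.22 to 2.06 for keratinocyte-like cells, -1.34 to -1.11 for cluster 31, -0.47 to -0.24 for Aire-high cells, 0.13 to 0.73 for Ccl21-high cells, -0.65 to 0.19 for cTECs and -0.37 to -0.01 for microfold-like cells.

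Within-line ratios of shares that moved were, in male cells, 0.887 (Aire-high, B5t), 0.900 (Ccl21-high, FoxN1), 1.37 and 0.456 (cTEC, FoxN1 and B5t), 2.74 (microfold-like, B5t) and 0 (tuft-like, FoxN1). Aire-high cells of the B5t line were at 0.786 from nearest cells and 0.768 when clustered without the differing genes, Ccl21-high cells of the B5t line at 1.99 at the mitochondrial limit, cluster 31 of the B5t line at 0.208 with the 5% removed, cTECs of the B5t line at 0.577 without low-UMI and mixed clusters, and microfold-like cells of the B5t line at 0.153 with doublets kept.

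With estimated correlations the adjusted p of lists past the threshold was 0.825 (Fezf2-associated, class II) and 0.970 (immediate-early) in Aire-high cells, 0.856 (keratinization, immediate-early) in Ccl21-high cells, 0.894 (immediate-early, tuft-cell) in cTECs, 0.480 (Fezf2-associated, chemokines, keratinization) and 0.853 (tuft-cell) in keratinocyte-like cells, and 0.251 (Fezf2-associated, tuft-cell) and 0.775 (keratinization, immediate-early) in all TECs. With the block by line, classical Aire-dependent antigens (0.0181) and mammary genes (0.00666) passed in cTECs, and keratinization in Aire-high cells changed its direction (0.867). Of the marker lists, the block ended the calls of enterohepatic markers in Ccl21-high cells (0.0651), of transit-amplifying and fibroblast markers in cTECs (0.0853 each) and of erythroid markers in all TECs (0.0671). It added calls of ciliated markers in Aire-high cells (0.0217), of tuft-like (0.00186), transit-amplifying (0.0391) and erythroid (0.0391) markers in Ccl21-high cells, of secretory markers in cTECs (0.0190), and of cTEC markers in keratinocyte-like cells (0.0397) and all TECs (0.00463).

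Across genes, r at a minimum mean of 100 CPM was 0.739 in Aire-high, 0.165 in Ccl21-high, -0.238 in cortical (Spearman rho 0.254) and 0.657 in keratinocyte-like cells and 0.556 in all TECs, and with a prior of 1 CPM it was 0.604 in Aire-high, -0.046 in cortical and 0.532 in keratinocyte-like cells. Genes at least 2-fold lower in both lines in Aire-high cells were 84, and at least 2-fold higher 76, with TMM-scaled CPM, and genes at least 2-fold higher in cTECs 12 with a prior of 1 CPM. Without each library in turn, Aire in Aire-high cells ranged from -0.21 to 0.05, with 0.02 without FoxN1_wt, and Foxn1 in cTECs from -0.22 without FoxN1_Cre to 0.955 without B5t_iCre.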

Other observations

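Of the explanations below, the tests of swapped libraries, of tags outside the deleted part, and of sex, cluster borders and doublets for the tuft-like and keratinocyte-like shares, and of sex for the immediate-early genes, apart from the medians in male cTECs, were chosen after the result was seen. Smaller groups of TECs had these values in FoxN1_wt, FoxN1_Cre, B5t_wt and B5t_iCre. Cells with liver and gut genes (enterohepatic-like) numbered 19, 3, 31 and 12, a log2 value of -1.95 in share (edgeR, adjusted p = 0.0763). Dividing cells, with Mki67, Top2a and Hmmr, in a sub-cluster whose most frequent class is cluster 31 of the report and so no separate group, numbered 48, 18, 82 and 48 (-1.10, 0.213), and ciliated-like cells 7, 14, 17 and 70 (1.501, 0.163). None of these passed. Another 3 TEC clusters came mostly from B5t_iCre. All were among the clusters left out in 1 alternative as of low UMI number or with genes of other cell types. Cluster 44, of cTECs, held 44 of its 48 cells there, at a median of 3130 UMIs per cell, and its leading genes include the thymocyte markers Cd8a and Cd8b1. Cluster 37, with the fibroblast or mesothelial marker Msln among its leading genes, held 8, 2, 10 and 64 cells, with a median of 2620 UMIs in B5t_iCre. Its log2 change in share was 1.33 (edgeR, adjusted p = 0.343), 2.01 without FoxN1_Cre and -1.29 without B5t_iCre. With classes from the nearest Cre-negative cells the change was -1.01 (edgeR, adjusted p = 0.292). Its ratio in the B5t line was 4.26 (2.17 to 9.31), but 0.445 (0.092 to 1.88) with those classes, and 9.585 (1.61 to 389) in male cells. Cluster 45 held 0, 0, 0 and 29 cells, at a median of 1982 UMIs (adjusted p = 0.220, but 0.00977 with the replicate block by line and 0.000257 without FoxN1_Cre), and was not found at a mitochondrial limit of 5% or in cells thinned to 2000 UMIs.

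Cells other than TECs differed in kind between the libraries. Dendritic cells were 4.35% of them in FoxN1_wt and 15.5% in FoxN1_Cre, against 7.23% in B5t_wt and 6.65% in B5t_iCre, and macrophages 10.9% and 20.1% against 11.9% and 11.8%. T cells were 41.1%, 38.4%, 29.6% and 17.6%.

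The higher Fezf2 counts in Aire-high cells with Cre were set against 3 technical explanations. A larger part of low-UMI cells in the class is excluded, since the lower of the lines' ratios was 2.24 within the main cluster of the class alone. A swap of the B5t libraries stays open. Psmb11, the gene named by the driver, had a ratio of 0.387 in B5t_iCre cTECs. That would speak against a swap only if the Cre allele lowers Psmb11, which the labels do not state. A swap of the FoxN1 libraries was not tested. Tags of a transcript that lost another part stay open: FoxN1_Cre cells held Fezf2 at 866.19 CPM at the 3-prime end, and no reads of the deleted part were used here. A biological explanation, such as higher activity of the Fezf2 promoter in cells that lack the protein, may also account for it and was not tested.

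Fewer tuft-like cells and a larger keratinocyte-like class with Cre, with 1 sub-cluster of secretory genes that passed (log2 3.05, adjusted p = 0.0196) and another (0.79, 0.456) and a cornifying one (0.04, 0.970) that did not, were set against 3 explanations. Sex is excluded as the whole cause, since the log2 change of the tuft-like share was -3.075 among male cells, and that of the keratinocyte-like share 1.79. Borders of clusters set by the differing genes stay open. With classes taken from the nearest Cre-negative cells the tuft-like share was at -2.875 and the keratinocyte-like share at 1.65. Those neighbours were found with the same genes, so these values cannot decide it. Clustered without the genes that differed in the tested classes, the tuft-like class kept 74 of its 75 cells, with a share at -2.85 (edgeR, adjusted p = 0.0217). Genes that differ within tuft-like cells were not tested, as these cells were too few. The cells of highest doublet score are not the source of the keratinocyte-like rise, which was 1.782 without them, although its adjusted p of 0.0893 (edgeR) then missed the threshold. Doublets among the remaining cells stay open, since the automatic threshold called few cells and the scores were not shown to mark all doublets. An effect of the loss of Fezf2 was not tested.

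Higher immediate-early genes with Cre in Aire-high, Ccl21-high and cortical cells were set against 2 explanations. The 95% intervals given here come from 1000 resamples of the cells and cover the spread of cells, not of libraries. Within these libraries, sex is excluded as the whole cause for cTECs. Their medians were 0.640 (0.381 to 0.886) in female cells of the FoxN1 line and 0.561 (0.211 to 0.858) in male cells of the B5t line. Male cTECs of the FoxN1 line, at 0.413 (0.012 to 0.915), do not decide it alone. Sex is likewise excluded as the whole cause for Ccl21-high cells of the B5t line, at 0.562 (0.301 to 1.04) in male cells. It stays open for Aire-high cells, at 0.42 (0.059 to 0.686) in male cells of the B5t line. In the FoxN1 line Aire-high cells were at 0.249 (-0.136 to 0.496) over all cells, 0.146 (-0.15 to 0.489) in female and 0.033 (-0.553 to 0.448) in male cells. Ccl21-high cells of that line were at 0.071 (-0.191 to 0.448) over all cells, 0.31 (-0.15 to 0.851) in female and -0.011 (-0.871 to 0.671) in male cells. All of these intervals of the FoxN1 line span 0. Handling of the cell suspension stays open: 2 of 6 classes of other cells had medians above 0.3 in both lines, and all 12 medians of these classes were above 0, from 0.17 to 0.98. The genotype and the handling of a library cannot be told apart with 1 library per group.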
